A study of Mus musculus with 12 samples.

How the data were processed

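Kidney RNA of wild-type mice was measured in 12 samples, 4 of each of CTL, HUA and XZSW. Per the labels' protocols, total RNA was taken with TRIzol, samples with an RNA integrity number over 7 were used, and libraries were strand-specific. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9 and aligned to GRCm38 with HISAT2 2.2.1; the counting tool, the annotation release and any filter were not given in the sources used here. The authors deposited a table with a raw count and an FPKM value per gene and sample, per the file headers. Its columns carry letters, C, N and M, which were matched to samples through the sample descriptions. These give C to the samples titled CTL, N to those titled HUA and M to those titled XZSW. The letters N and M do not abbreviate the group names, and no other label checks the match. If they were exchanged, the HUA and XZSW values given here would be exchanged too.

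The table held 33188 genes, of which 730 were 0 in every sample. Of the gene identifiers 122 shared their symbol with another, so genes were followed by identifier. Of the identifiers 33092 were found in a GRCm38 gene annotation and 32924 at the same chromosome and start. Totals were 51.6 to 74.3 M counts per library. The deposited FPKM values followed the counts. After a factor per library, the ratio of count to FPKM of a gene had a median coefficient of variation across libraries of 0.0358%, over 8419 genes. Counts of replicates varied more than counting error allows, with a chi-square per degree of freedom of 25.8 to 453 between pairs of libraries. A plan written before the data were examined had set a test for FPKM values with a switch to edgeR if counts were present; counts were present and edgeR was used.

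Genes were kept by edgeR's filterByExpr with group as the factor, which left 19772. Counts were scaled by TMM (factors 0.856 to 1.15) and tested with edgeR's quasi-likelihood F-test over all 12 libraries, with a prior of 4.23 degrees of freedom, for HUA against CTL, XZSW against HUA and XZSW against CTL. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes; rose and fell are used only for such genes. Standard errors of log2 changes were taken from the F statistic. Levels are CPM with TMM factors, as mean ± SD over 4 libraries. Where a group had 0 counts, a lower bound of the fold was computed with a floor of 3 counts. Exact permutation tests of the genes in the series title used log2(FPKM + 1). R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

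The 48 gene lists, the comparisons, the tests, the thresholds and the rule for named genes were chosen before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at a correlation estimated per list and with fry, each adjusted over 48 lists; lists with fewer than 5 tested members would only have been described. Named genes were the 10 largest rises and 10 largest falls of each comparison among called genes with a mean FPKM of at least 2 in the higher group, all libraries of the groups apart and no predicted-gene name, the 5 genes of the series title, and the 4 members with the smallest p of each list. Havcr1, Xdh and the other genes said to be named after their values were seen are exceptions, and some genes that the rule names are not reported here. The lists covered macrophage, neutrophil, T and NK cell and B and plasma cell markers, tubular injury, urate transport, purine metabolism, matrix, cytokines, inflammasome, complement, SRC and FAK signalling, Wnt and beta-catenin, SPP1 receptors and CD44 ligands, nephron segments and kidney cell types, neighbouring tissues and blood, energy and amino acid metabolism, stress, interferon, antigen presentation, cell cycle, clock, hormone and xenobiotic responses, sex chromosome genes, apoptosis and ribosomal proteins.

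Scripts were tested on simulated data with 50 changed genes per fold, drawn from genes above a minimum CPM, and the same spread per gene in all groups. In the data the spread differed between groups and far more genes were called. The recovered shares given next are therefore not the power of the 3 real comparisons. Of genes changed 2-fold 42%, 38% and 50% were recovered in the 3 comparisons, of those changed 1.5-fold 12%, 4% and 8%, and of those changed 4-fold 90.0%, 88% and 94%, with 8, 8 and 7 false calls. A shifted list was called and 0 of 40 random lists were. Each comparison was repeated for all 35 splits of its 8 libraries 4 and 4.

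Alternatives set beforehand were other filters, pseudocounts, scalings and tests, fits on the 8 libraries of a comparison, a replicate block and leaving out each library in turn. Chosen after the data were seen were library-total scaling and limma on log2(FPKM + 1) beside edgeR. The plan had set this limma test as the main test for a table without counts. A correction of each library for transcript GC content and length by loess offsets was also chosen after the data were seen. So were the GC split as a further term of the fit and fits within each side of the split at a slope of 0.2. GC slopes were fitted over 14635 genes against the CTL mean. Genes whose reads map to near copies, among them mitochondrial genes with nuclear copies, were kept and are named as uncertain. No sample was left out.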

Results

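RNA was measured in mouse kidney, in 12 strand-specific libraries of wild-type animals that fell into 3 groups of 4. CTL was the control group. HUA was the hyperuricemia model, made with potassium oxonate, an inhibitor of uricase, and hypoxanthine, a purine that is converted to uric acid. XZSW was the same model given Xin-Zi-Sheng-Wan, a decoction of traditional Chinese medicine. Library totals ranged from 51.6 to 74.3 M counts, with means of 58.9 ± 5.44 M in CTL, 67.3 ± 7.69 M in HUA and 66.1 ± 5.66 M in XZSW (mean ± SD, n = 4). Of 33188 genes in the table, 19772 had enough counts to be tested. No label says that the 4 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Correlations between libraries on the log scale, over genes, were 0.961 to 0.966 within CTL, 0.935 to 0.959 within HUA and 0.942 to 0.968 within XZSW.

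The libraries differed in composition in ways that the groups explained only in part. Genes of the mitochondrial genome took 13.1 ± 1.44% of counts in CTL, 9.47 ± 1.75% in HUA and 16.1 ± 1.77% in XZSW (mean ± SD, n = 4). In 5 libraries (HUA2, HUA3, HUA4, XZSW3 and XZSW4), genes of high GC content were higher and genes of low GC content lower than in CTL, with slopes of 0.240 to 0.365 log2 units per 10% GC. The 4 CTL libraries, HUA1, XZSW1 and XZSW2 had slopes of -0.0447 to 0.0772. In HUA1, XZSW1 and XZSW2 longer transcripts were higher than in CTL, with slopes of 0.245, 0.178 and 0.129 log2 units per doubling of length; the slopes were -0.0068 to 0.0093 in CTL and -0.0424 to 0.101 in the other 5. This split crossed the HUA and XZSW groups and was found after the data were seen, so counts are also given with it as a further term of the fit. Slopes were taken against the CTL mean, and all 4 CTL libraries fell on the side of HUA1, XZSW1 and XZSW2. The term thus rests on HUA and XZSW alone. With it, comparisons with CTL lean on HUA1, XZSW1 and XZSW2, which have the length trend. It therefore cannot free these comparisons from differences between kinds of library. Genes of tissues next to the kidney were counted as well. None of 5 adrenal cortex genes rose and 1 fell in HUA against CTL. Of 6 tested skeletal muscle genes 1 rose and 1 fell; adjusted over the list alone the numbers were the same. Of 8 tested adipocyte genes none passed in HUA against CTL and 2 rose in XZSW against HUA, Car3 and Thrsp, also adjusted over the list alone, and none with the GC split as a further term. Of the 12 listed adipocyte genes 11 had their highest value in XZSW1. Of the muscle genes 1 rose in XZSW against HUA, Pvalb, which the distal tubule also expresses, and 1 rose and 1 fell adjusted over the list alone. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were measured in every group, at 36.2 ± 20.2 CPM for Ddx3y in HUA, 57.0 ± 1.86 in CTL and 41.5 ± 14.0 in XZSW, and Xist stood at 0.512 to 2.996 CPM on average. Of the 5 sex chromosome genes, 1 fell in HUA against CTL and 0 fell adjusted over the list alone.

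**Figure D1:**
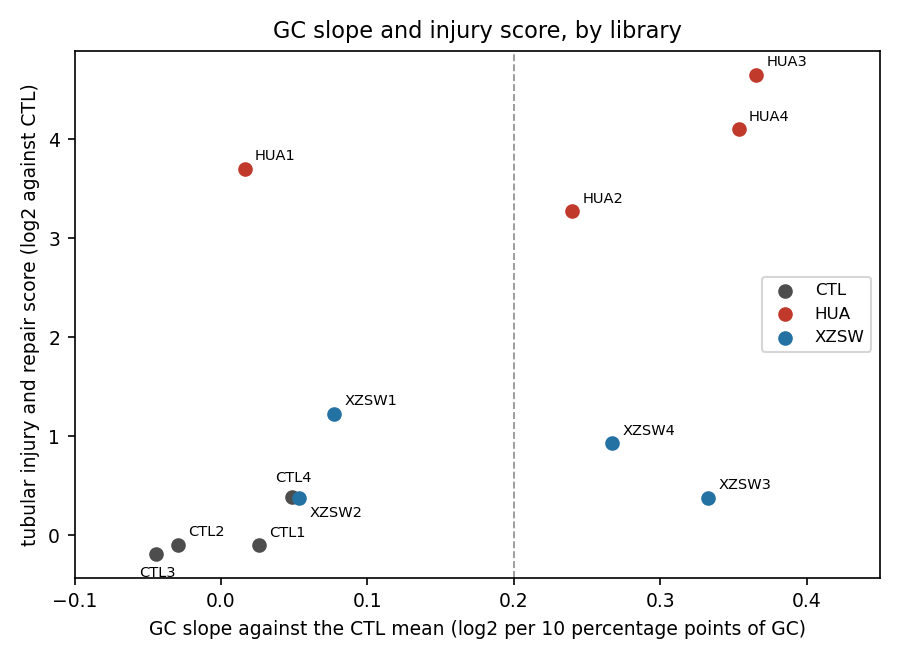
Score of the tubular injury and repair list (vertical axis, log2 units relative to CTL) in the 12 libraries, 1 point each. The horizontal axis is the slope of expression on GC content (log2 units per 10% GC, relative to the CTL mean). A dashed vertical line marks a slope of 0.2. The 5 libraries to the right of the line are 3 of HUA and 2 of XZSW. HUA1 lies to its left at an injury score of 3.70.

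The comparison of HUA with CTL asks what the hyperuricemia model did to kidney expression. All 26 genes of the tubular injury and repair list rose in HUA, with a median log2 change of 3.69. Lcn2, which encodes the injury marker NGAL, rose from 1.92 ± 1.17 to 433.2 ± 229.6 CPM (mean ± SD, n = 4; log2 change 7.81, SE 0.77). Havcr1, which encodes the injury marker KIM-1 and is named here after its values were seen, rose from 37.9 ± 5.60 to 1141 ± 913 CPM. Of the macrophage markers 15 of 20 rose, of the cytokine and chemokine genes 19 of 27 and of the complement genes 11 of 16, while 10 of 16 urate and organic anion transport genes fell, among them Slc22a12 and Slc17a3 (with an estimated correlation, adjusted p = 0.218, 0.144, 0.0715 and 0.218). In all, 5488 of the 19772 genes changed (27.8%), 2950 upward and 2538 downward.

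The genes with the largest rises in HUA were absent or almost absent from CTL. Vgf, a secreted neuropeptide precursor, Prss22, a serine protease, and Arhgap36, a regulator of hedgehog signalling, had 0 counts in the 4 CTL libraries and were at least 5487-fold, 799.6-fold and 543-fold higher in HUA, against a floor of 3 counts over the group. Spaca7 was likewise at least 139.6-fold higher. Sprr2g, a cornified envelope protein, rested on 3 counts in CTL and had a count ratio of 846 (95% interval 289 to 4100, which covers counting error only). Its neighbour Sprr2f shares sequence with it, so both values are uncertain. The cytokines Il1f6 and Lif rose to 109.4 ± 82.0 and 100.1 ± 96.9 CPM, from means of 0.0545 and 0.259 CPM, and Wnt7a rose with a log2 change of 8.69 (SE 1.71). The spread of these values was wide: Vgf stood at 237.9 CPM in HUA3 and at 22.6 CPM in the lowest HUA library. All CTL counts of Il1f6 and Wnt7a came from CTL2 and those of Sprr2g from CTL3, and without these libraries CTL was at 0 and no log2 change can be given. Without HUA3 the log2 changes of Il1f6 and Wnt7a were 10.32 and 7.94 in place of 10.97 and 8.69, and without CTL3 that of Sprr2f was 8.53 in place of 7.91. That of Lif was 7.80 without HUA1 and 9.24 without CTL2, in place of 8.61. All of these genes stayed past the threshold in each of the 12 omissions.

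Among the largest falls in HUA, Anxa13, an annexin of polarised epithelium, fell 13.9-fold (adjusted p = 5.61e-05), and the organic anion transporter Slc22a7 fell from 98.3 ± 24.8 to 8.17 ± 10.5 CPM, a log2 change of -3.59 that became -5.01 without HUA2. The lipase gene Lpl fell from 528 ± 84.5 to 54.5 ± 28.6 CPM, and the mitochondrial carrier Slc25a25 from 815 ± 98.6 to 86.8 ± 37.6 CPM. Ccl28, a mucosal chemokine, fell 9.95-fold, Slc4a1, the anion exchanger of intercalated cells and red cells, 8.91-fold, and Snx31 and G0s2, an inhibitor of lipolysis, 10.2-fold and 9.71-fold. Without HUA2 the log2 changes of Snx31, G0s2 and Slc4a1 were -4.03, -4.03 and -3.95 in place of -3.35, -3.28 and -3.16. Cyp2d12 and Ugt1a6b fell 11.2-fold and 12.05-fold, but both have close paralogs and their reads may be split between copies.

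Within the tubular injury list, the epithelial keratins Krt18 and Krt8 rose 18.04-fold and 5.93-fold, the secreted chaperone Clu rose from 166 ± 15.9 to 3572 ± 1460 CPM, and Sox9, a transcription factor of tubule repair, rose 45.2-fold (camera adjusted p = 1.46e-38, and adjusted p = 0.0447 with an estimated correlation). This was the list in HUA against CTL whose call held with an estimated correlation. Of the 20 macrophage markers, 15 rose, 1 fell and 4 did not pass, and 16 rose and 1 fell adjusted over the list alone. Cd14 rose from 5.34 ± 1.87 to 134 ± 80.1 CPM, and Cd68 and Itgam, the integrin chain CD11b, rose 6.38-fold and 16.9-fold (camera adjusted p = 1.28e-07, and adjusted p = 0.218 with an estimated correlation). Of 27 cytokine and chemokine genes, 19 rose and 1 fell, and 21 and 1 adjusted over the list alone, with Csf1, the growth factor of macrophages, up 14.1-fold and Cxcl16 up 3.43-fold (camera adjusted p = 7.59e-07, and adjusted p = 0.144 with an estimated correlation). Of 16 complement genes, 11 rose and 2 fell, the same numbers adjusted over the list alone. C3 rose from 25.6 ± 11.9 to 782 ± 335.5 CPM and Cfi 9.92-fold (adjusted p = 0.0715 with an estimated correlation).

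Matrix, interferon and antigen presentation genes rose in part. In the extracellular matrix and fibrosis list, 18 of 30 genes rose and none fell, 19 adjusted over the list alone, with Fn1 (fibronectin) up 5.70-fold and Tnc 38.3-fold (camera adjusted p = 1.86e-09, and adjusted p = 0.334 with an estimated correlation). In the interferon response list, 15 of 22 rose, 17 adjusted over the list alone, with Irf1 up 3.31-fold and Gbp3 5.05-fold (adjusted p = 0.334 with an estimated correlation). In the antigen presentation list, 10 of 14 rose, 13 adjusted over the list alone, with H2-DMb1 up 5.12-fold (adjusted p = 0.334 with an estimated correlation). Of 19 apoptosis and cell death genes 11 rose, the same number adjusted over the list alone, among them Pmaip1 and Ripk3 (camera adjusted p = 0.000216, and adjusted p = 0.144 with an estimated correlation). Of 19 immediate early and dissociation stress genes 11 rose and 1 fell, with the same numbers adjusted over the list alone and with Socs3 up 70.6-fold and Klf6 9.30-fold (camera adjusted p = 0.000212, and adjusted p = 0.476 with an estimated correlation). Of 22 cell cycle genes 6 rose, also adjusted over the list alone, among them Tpx2 and Mcm6 (camera adjusted p = 0.0185, and adjusted p = 0.684 with an estimated correlation). With the GC split as a further term 1 rose and camera gave adjusted p = 0.226. The score of the cell cycle list, in log2 units relative to CTL, was 2.25 in HUA4. It was 0.355, 0.853 and 0.055 in HUA1, HUA2 and HUA3 and -0.463 to 0.254 in CTL.

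Of 20 genes of segments S1 and S2, 15 fell and none rose, 18 adjusted over the list alone, with a median log2 change of -1.49. Slc22a6 and Slc22a8, the organic anion transporters OAT1 and OAT3, fell 4.74-fold and 4.999-fold, and Kap, an androgen-regulated kidney protein, from 26002 ± 2522 to 7226 ± 3570 CPM (camera adjusted p = 1.65e-11, and adjusted p = 0.218 with an estimated correlation). Of 12 genes of segment S3, 9 fell, 10 adjusted over the list alone, with Cyp4b1 down 4.06-fold and Acsm3 7.20-fold (adjusted p = 0.218 with an estimated correlation). Of 16 urate and organic anion transport genes, 10 fell and 1 rose, 11 and 1 adjusted over the list alone. Slc22a12, the urate reabsorption transporter URAT1, fell from 1466 ± 272.5 to 449 ± 162 CPM, Slc17a3 3.77-fold and Slc17a1 2.48-fold (camera adjusted p = 2.17e-09, and adjusted p = 0.218 with an estimated correlation). The androgen-dependent kidney genes, many of them genes of the same segments, had 13 of 18 falling and 1 rising, 14 and 1 adjusted over the list alone, with Slco1a1 down 5.37-fold (adjusted p = 0.144 with an estimated correlation).

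In the PPAR alpha and fatty acid oxidation list 23 of 28 genes fell and 1 rose, the same numbers adjusted over the list alone, with a median log2 change of -1.21. With the GC split as a further term 10 fell and none rose, with a median of -0.74. Acadm, the medium-chain acyl-CoA dehydrogenase, fell from 1155 ± 95.7 to 350.4 ± 146 CPM and Cpt2 2.48-fold (camera adjusted p = 8.04e-12, and adjusted p = 0.218 with an estimated correlation). In the nuclear respiratory chain list 20 of 28 fell, 21 adjusted over the list alone, with Uqcrc2 down 1.82-fold and Ndufv1 1.75-fold (adjusted p = 0.324 with an estimated correlation). With library-total scaling 12 of these fell. Of 13 genes of the mitochondrial genome 11 fell, 12 adjusted over the list alone, and mt-Cytb fell 1.97-fold (adjusted p = 0.334 with an estimated correlation). After correction for GC content and length 6 fell, with a median of -0.52 in place of -0.83, with the GC split as a further term 5 fell, and with library-total scaling 7. Single mitochondrial genes are uncertain, since nuclear copies of mt-Co3 and mt-Atp6 had counts in ratios of 0.990 to 1.00 and 1.04 to 1.06 to them in the 12 libraries. In the gluconeogenesis and amino acid metabolism list 15 of 20 fell and 1 rose, as adjusted over the list alone, with Pcx, pyruvate carboxylase, down 2.71-fold and Asl 2.51-fold (adjusted p = 0.218 with an estimated correlation).

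Of 12 intercalated cell genes 6 fell and 3 rose, as adjusted over the list alone, with Rhcg down 3.26-fold and Slc26a4 2.46-fold (camera adjusted p = 0.0257, and adjusted p = 0.501 with an estimated correlation). After correction for GC content and length camera gave adjusted p = 0.0534. Of 12 podocyte genes 5 rose and 1 fell, as adjusted over the list alone, with Nphs1, which encodes nephrin, up 1.69-fold (camera adjusted p = 0.046, and adjusted p = 0.511 with an estimated correlation). After the same correction it gave adjusted p = 0.122. Of 9 erythroid and blood genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone, and Hbb-bt, whose reads are shared with Hbb-bs, fell 8.85-fold (adjusted p = 0.347 with an estimated correlation). After correction for GC content and length 2 of these fell and 1 rose, with camera's adjusted p at 0.049, and with the GC split as a further term 3 fell and 1 rose (adjusted p = 0.0275). Haemoglobin genes took 0.0384 ± 0.0074% of counts in CTL and 0.0074 ± 0.0096% in HUA (mean ± SD, n = 4). Neutrophil markers were close to the detection limit, with 2 of 9 rising and 3 adjusted over the list alone (camera adjusted p = 0.083); S100a9 rose to 2.05 ± 2.13 CPM. Of 13 T and NK cell markers 1 fell, Trac, and none adjusted over the list alone. Of 10 B and plasma cell markers 1 rose and 2 fell, as adjusted over the list alone, among them Igkc, which fell 2.61-fold. The median of this list was -0.21 and its mean 0.18, with camera's direction down at an adjusted p of 0.415. Of 15 endothelial genes 1 rose and 1 fell, Nos3 and Kdr, and none adjusted over the list alone. Of 15 fibroblast, pericyte and smooth muscle genes 5 rose and 1 fell, as adjusted over the list alone, with Col1a1 up 12.9-fold (camera adjusted p = 0.415 and 0.238). In the fit with the GC split as a further term 2 of the last list rose and none fell, with a median of 0.04 in place of 0.52, and no B and plasma cell or endothelial gene passed.

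Camera called neither the purine metabolism list nor the inflammasome list. Of 23 purine metabolism genes 7 rose and 3 fell, as adjusted over the list alone, with Ampd3 up 2.75-fold and Adk down 1.91-fold (camera adjusted p = 0.481). With library-total scaling 10 of these rose and 1 fell. Xdh, which encodes the xanthine oxidoreductase that makes uric acid and is named after its values were seen, rose from 12.6 ± 3.18 to 24.6 ± 4.13 CPM (adjusted p = 0.0136). Of 12 inflammasome and pyroptosis genes 5 rose and 1 fell, 5 and 2 adjusted over the list alone, with Casp4 up 7.83-fold and Il1b 7.20-fold (camera adjusted p = 0.34). In the fit with the GC split 2 of these rose and 1 fell. In all, camera called 23 of 48 lists, 13 up and 10 down, and 1 of these held with an estimated correlation; fry, which asks whether a list's genes move 1 way on balance, called 26.

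With library-total scaling, which moved the median log2 change of 14643 genes by 0.32 relative to the main scaling, 5779 genes rose and 1320 fell. On the deposited FPKM values 5673 rose and 1414 fell. With the GC split as a further term 4728 genes changed, 3394 of them shared with the 5488 and all of these in the same direction. With this term fewer members rose in the macrophage (10), interferon (8), antigen presentation (5) and immediate early (7) lists and fewer fell in the S3 (5) and gluconeogenesis (9) lists. With library-total scaling 14 cell cycle and 18 apoptosis genes rose.

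The series title names 5 genes, Spp1, Cd44, Src, Ptk2 (which encodes the focal adhesion kinase FAK) and Ctnnb1 (which encodes beta-catenin). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, GRCm38) encodes the secreted phosphoprotein osteopontin, a ligand of integrins and of CD44. It stood at 512 ± 52.1 CPM in CTL, 20516 ± 16670 CPM in HUA and 1167 ± 258 CPM in XZSW (mean ± SD, n = 4). It rose 40.1-fold in HUA against CTL (log2 change 5.32, SE 0.52, adjusted p = 3.81e-05) and fell 17.6-fold in XZSW against HUA (log2 change -4.14, SE 0.49, adjusted p = 0.00047). Without HUA4, the highest library, the log2 changes were 4.64 and -3.43. Cd44 (ENSMUSG00000005087, chromosome 2, 102811141 to 102901665) went from 3.82 ± 1.56 to 43.4 ± 23.5 and back to 6.36 ± 1.51 CPM, a rise of 11.3-fold and a fall of 6.83-fold. Src (ENSMUSG00000027646, chromosome 2, 157418444 to 157471838) stood at 31.6 ± 4.58, 59.3 ± 14.2 and 31.5 ± 3.66 CPM, a rise of 1.88-fold (adjusted p = 0.00195) and a fall of 1.88-fold (adjusted p = 0.00461). Ptk2 (ENSMUSG00000022607, chromosome 15, 73205102 to 73423212) passed in none of the 3 comparisons, with log2 changes of 0.23, -0.16 and 0.07 (SE 0.16 each). Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507) missed the threshold in HUA against CTL (log2 change 0.39, SE 0.14, adjusted p = 0.0521). It passed there with quantile normalization (adjusted p = 0.00168), with TMM factors on the FPKM values (0.0457), with the GC split as a further term (0.0324) and with library-total scaling (0.00251). It also passed without HUA2, HUA4 or XZSW3. Ptk2 passed in HUA against CTL with library-total scaling (adjusted p = 0.0175). Ctnnb1 fell in XZSW against HUA (log2 change -0.56, SE 0.14, adjusted p = 0.0178), though not without XZSW2, where the log2 change was -0.52 (adjusted p = 0.0546).

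With all 12 libraries, none of the 5 genes passed between XZSW and CTL by edgeR's test (2 by an exact test on the FPKM values). The log2 change of Spp1 was 1.19 (SE 0.44, adjusted p = 0.129), with all 4 XZSW libraries above all 4 CTL libraries. Spp1 passed there without HUA2 (adjusted p = 0.047), without HUA4 (0.035) and within the 7 libraries without the GC trend (0.0121). The log2 change of Cd44 was 0.73 (SE 0.35, adjusted p = 0.232). In a two-sided exact permutation test on log2(FPKM + 1) of 4 against 4 libraries, which has 70 arrangements, all 5 genes had p = 0.0286 in HUA against CTL, the smallest this design allows (0.039 after adjustment over 15 tests). In XZSW against HUA the exact p was 0.0286 for Spp1, Cd44, Src and Ctnnb1 and 0.2 for Ptk2 (0.231 after adjustment). In XZSW against CTL it was 0.0286 for Spp1 and Ptk2, 0.0571 for Cd44, 0.286 for Src and 0.657 for Ctnnb1. The FPKM values carry no correction for composition, and their median log2 change over 14643 genes was 0.23 in HUA against CTL, beside 0.01 with the scaling used for the counts. Within the 5 libraries with the GC trend, 3 of HUA and 2 of XZSW, none of the 5 genes passed in XZSW against HUA, with log2 changes of -4.08 for Spp1 and -2.90 for Cd44. Within the other 7, where HUA is 1 library and the spread comes from CTL and XZSW alone, Spp1, Cd44 and Ctnnb1 passed and Src did not (log2 change -0.73, adjusted p = 0.0523).

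**Figure D2:**
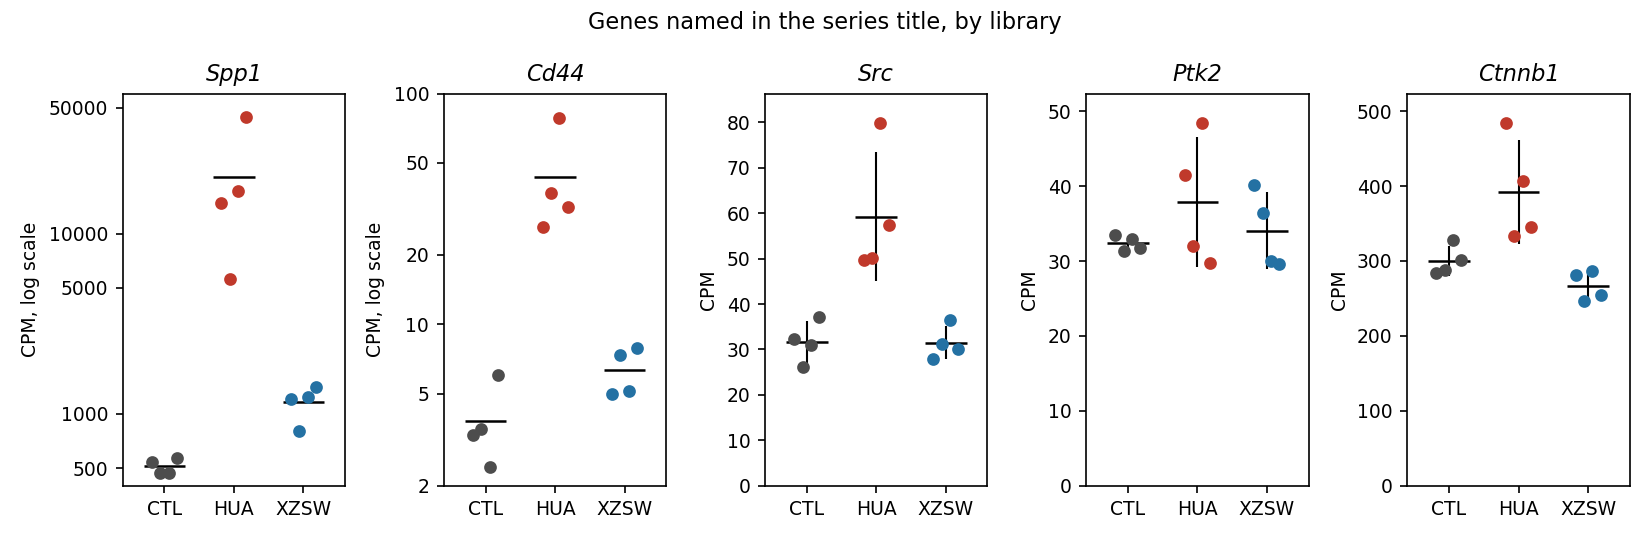
Normalised read counts (CPM, vertical axes) of the 5 genes of the series title in each of the 12 libraries, in 1 panel per gene, with Spp1 and Cd44 on logarithmic axes; points are libraries, horizontal lines group means and vertical bars SD in the linear panels. Means of Spp1 were 512, 20516 and 1167 CPM in CTL, HUA and XZSW, and those of Ptk2 32.4, 37.9 and 34.1 CPM.

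The pathways around these genes moved in part in HUA against CTL. Their lists hold the title genes themselves. Spp1 and Cd44 are in the list of SPP1 receptors and CD44 ligands and in the tubular injury list. Src and Ptk2 are in the SRC and FAK list and Ctnnb1 in the Wnt and beta-catenin list. Spp1, Cd44 and Src are thus among the genes counted as rising. Of 14 genes of SPP1 receptors and CD44 ligands 7 rose and 1 fell, 9 and 1 adjusted over the list alone, with the integrin chains Itga5 and Itgb3 up 3.37-fold and 4.398-fold (camera adjusted p = 0.00114, and adjusted p = 0.144 with an estimated correlation). Of 32 SRC and FAK adhesion signalling genes 18 rose and none fell, as adjusted over the list alone, with Actn1 up 8.83-fold, Itga3 4.03-fold, the Src-family kinase Fgr 7.53-fold and Zyx 2.05-fold (camera adjusted p = 2.11e-06, and adjusted p = 0.334 with an estimated correlation). Of 34 Wnt and beta-catenin genes 5 rose and 2 fell, as adjusted over the list alone (camera adjusted p = 0.418). Those that rose included the target genes Myc and Mmp7, 8.83-fold and 25.5-fold, and Cdh1 (E-cadherin), 2.29-fold, while the target gene Sp5 fell 2.42-fold. With library-total scaling 9 Wnt and beta-catenin genes rose and 2 fell, 27 SRC and FAK genes rose, and 10 genes of SPP1 receptors and CD44 ligands rose and none fell.

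The comparison of XZSW with HUA asks what the decoction did to the model. Of the 26 injury genes 24 fell and none rose, with the same number adjusted over the list alone and a median log2 change of -3.32. Krt18 fell from 462 ± 112 to 60.0 ± 21.3 CPM (mean ± SD, n = 4), Ccn1, a matricellular protein, from 531 ± 124 to 32.5 ± 6.22 CPM, and Sox9 33.3-fold (camera adjusted p = 1.53e-45, and adjusted p = 0.0266 with an estimated correlation). Of the 20 proximal tubule S1 and S2 genes 17 rose and none fell, 18 adjusted over the list alone, with Slc22a8 up from 90.9 ± 31.6 to 566 ± 225.7 CPM (adjusted p = 0.253 with an estimated correlation). Over all genes, 3051 of 19772 changed, 1402 upward and 1649 downward.

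The largest rises in XZSW against HUA were in Commd1b, Car3, Slc4a1, Cyp2d12 and Anxa13. Commd1b had 0 counts in the 4 HUA libraries and was at least 1499-fold higher in XZSW, though its near-identical parent gene Commd1 leaves its counts uncertain. It did not pass on the FPKM values, with TMM factors (adjusted p = 0.087) or with limma on log2(FPKM + 1) (adjusted p = 0.0746). Car3, a carbonic anhydrase also made by fat cells, rose 18.4-fold in a mean set by XZSW1, at 198 CPM, and did not pass without that library (log2 change 2.46 in place of 4.20, adjusted p = 0.0515). Commd1b stood at 1.78 to 39.8 CPM in the XZSW libraries. Without HUA2 the log2 change of Car3 was 5.85. Car3 and Hpd did not pass with the GC split as a further term, and Hpd did not after correction for GC content and length. Slc4a1 rose 10.2-fold, Cyp2d12 9.80-fold, Anxa13 7.34-fold, Bhmt, an enzyme of methionine metabolism, 6.83-fold, and Pde6a 5.63-fold. Without HUA2 the log2 changes of Slc4a1 and Pde6a were 4.16 and 3.72 in place of 3.34 and 2.49. Hpd, an enzyme of tyrosine breakdown, rose 5.60-fold (adjusted p = 0.0399) but lost its call in 7 of the 12 omissions of a library, and Clec2h rose 5.60-fold but had an adjusted p of 0.0505 without HUA3. Without HUA2 their log2 changes were 3.20 and 3.24 in place of 2.49 and 2.48.

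Among the largest falls in XZSW against HUA, Vgf fell 186-fold, the cytokines Lif and Il1f6 fell 75.7-fold and 66.7-fold, the chemokine Ccl20 59.4-fold and Nppb, which encodes brain natriuretic peptide, 86.3-fold from 4.73 ± 6.08 CPM. The transcription factors Fosl1 and Atf3 fell 41.7-fold and 38.1-fold, and Krt20 39.5-fold. Ankrd1, a target of YAP signalling, fell from 102.3 ± 18.2 to 2.66 ± 0.956 CPM (log2 change -5.26, SE 0.26, adjusted p = 5.27e-07), the smallest adjusted p among the named genes of this comparison. The small Mir6358 fell 70.8-fold from 1.22 ± 1.13 CPM. Nppb did not pass on the FPKM values with TMM factors or with limma on log2(FPKM + 1). Single libraries moved several of these values without ending a call. Without HUA3 the log2 changes of Vgf, Il1f6 and Krt20 were -5.91, -5.39 and -3.92 in place of -7.54, -6.06 and -5.30, and without HUA1 those of Nppb, Lif, Fosl1 and Atf3 were -5.11, -5.42, -4.53 and -4.32. Without XZSW1 those of Vgf, Nppb, Il1f6, Ccl20 and Fosl1 were -10.65, -7.68, -8.01, -6.65 and -7.67, and without HUA4 that of Mir6358 was -5.39.

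Along the nephron, 7 of 12 intercalated cell genes rose and none fell, 9 adjusted over the list alone, with Rhcg up from 19.8 ± 7.79 to 99.5 ± 24.8 CPM and Insrr 5.51-fold (camera adjusted p = 2.67e-08, and adjusted p = 0.22 with an estimated correlation). Of 12 collecting duct principal cell genes 4 rose, 5 adjusted over the list alone, among them Hsd11b2 (4.05-fold) and the water channel Aqp3 (3.54-fold; adjusted p = 0.253 with an estimated correlation). Of 12 distal convoluted and connecting tubule genes 6 rose and 1 fell, as adjusted over the list alone, with Wnk4 up 2.02-fold and the calcium channel Trpv5 down 2.19-fold (adjusted p = 0.278 with an estimated correlation). Of 12 segment S3 genes 3 rose, as adjusted over the list alone, with Cyp4b1 up 2.52-fold (camera adjusted p = 0.00845, and adjusted p = 0.462 with an estimated correlation). Of 16 urate and organic anion transport genes 7 rose, 8 adjusted over the list alone, with Slc22a6 up 3.24-fold, Slc17a3 2.17-fold and the scaffold gene Pdzk1 2.22-fold (camera adjusted p = 7.05e-07, and adjusted p = 0.253 with an estimated correlation). Of 20 gluconeogenesis and amino acid metabolism genes 14 rose and 1 fell, 15 and 2 adjusted over the list alone. Prodh2 rose 2.68-fold and Arg2 fell 6.78-fold (adjusted p = 0.253 with an estimated correlation).

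Of 13 genes of the mitochondrial genome 12 rose, 13 adjusted over the list alone, with mt-Nd4 up 2.61-fold (adjusted p = 0.253 with an estimated correlation). Of 28 nuclear respiratory chain genes 13 rose, 16 adjusted over the list alone, with Ndufa10 up 1.60-fold (adjusted p = 0.453 with an estimated correlation). With library-total scaling 5 of these 28 rose. In the fatty acid oxidation list 4 of 28 rose and 3 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.16), and 2 rose and 3 fell with the GC split as a further term. Acaa2, a thiolase of the pathway, rose 1.93-fold, while Pdk4, a kinase that restrains pyruvate oxidation, Angptl4, an inhibitor of lipoprotein lipase, and Plin2, a lipid droplet protein, fell 5.47-fold, 2.75-fold and 8.61-fold. Ribosomal protein genes had 8 of 24 falling, 23 adjusted over the list alone, with Rps24 down 1.83-fold (camera adjusted p = 3.22e-07, and adjusted p = 0.462 with an estimated correlation). With library-total scaling 18 fell and after correction for GC content and length 19, with a median of -0.55 in place of -0.58. The list's score, in log2 units relative to CTL, was lowest in the 3 libraries with the steepest length slopes, at -0.233 in HUA1, -0.555 in XZSW1 and -0.328 in XZSW2. It was 0.099, 0.504 and 0.793 in HUA2, HUA3 and HUA4 and -0.093 and -0.072 in XZSW3 and XZSW4. In HUA against CTL 3 of these 24 had risen and none adjusted over the list alone, among them Rps24 (camera adjusted p = 0.0548). With library-total scaling 19 rose there, after correction for GC content and length 12 rose and 1 fell, and with the GC split as a further term none rose and 1 fell.

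Some members of the inflammatory and stress lists fell in XZSW against HUA, while no lymphocyte marker did. Of 10 B and plasma cell markers 1 rose, none adjusted over the list alone, with a median log2 change of 1.35 (camera adjusted p = 0.0225, and adjusted p = 0.444 with an estimated correlation). None of 13 T and NK cell markers passed, with a median of 0.98 (camera adjusted p = 0.22). Of 20 macrophage markers 4 fell, as adjusted over the list alone, among them Cd14, from 134 ± 80.1 to 12.5 ± 3.75 CPM, C1qb and Cd68, 2.52-fold and 2.02-fold (camera adjusted p = 0.00545, and adjusted p = 0.486 with an estimated correlation). Of 27 cytokine and chemokine genes 8 fell and 1 rose, 8 and 2 adjusted over the list alone, with Csf1 down 6.05-fold and Il34, which binds the same receptor, 6.79-fold (adjusted p = 0.253 with an estimated correlation). Of 16 complement genes 5 fell, 7 adjusted over the list alone, with C3 down 8.81-fold (adjusted p = 0.253 with an estimated correlation). Of 30 matrix genes 11 fell, 13 adjusted over the list alone, with Tgfb1 down 2.63-fold (adjusted p = 0.462 with an estimated correlation). Of 19 immediate early and dissociation stress genes 12 fell, 15 adjusted over the list alone, with Jun down 4.33-fold, Klf6 11.2-fold and Socs3 22.7-fold (camera adjusted p = 5.52e-12, and adjusted p = 0.253 with an estimated correlation). Of 19 apoptosis and cell death genes 7 fell, 12 adjusted over the list alone, among them Cdkn1a and Mlkl, with log2 changes of -3.46 and -2.52 (adjusted p = 0.0846 with an estimated correlation). With library-total scaling 12 of these fell and after correction for GC content and length 11. In the SRC and FAK list 12 of 32 fell, 15 adjusted over the list alone, with Itgb1 down 1.998-fold and Zyx 2.27-fold (adjusted p = 0.278 with an estimated correlation). In the list of SPP1 receptors and CD44 ligands 6 of 14 fell, also adjusted over the list alone (adjusted p = 0.201 with an estimated correlation). Spp1 and Cd44 are themselves among these 6, and Src is among the 12 of the SRC and FAK list. In the Wnt and beta-catenin list 2 of 34 rose and 4 fell, 4 and 4 adjusted over the list alone, with Myc down 6.01-fold and Notum up 2.80-fold (camera adjusted p = 0.946). Ctnnb1 itself is among those that fell. In all, camera called 28 of 48 lists, 14 in each direction, of which 1 held with an estimated correlation, and fry called 20.

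With library-total scaling 836 genes rose and 2714 fell, and on the FPKM values 1184 rose and 2387 fell. With library-total scaling 18 SRC and FAK genes fell and 13 S1 and S2 genes and 2 S3 genes rose. Within the 5 libraries with the GC trend, 3 of HUA against 2 of XZSW, 41 genes changed. With the split as a further term 3628 changed, 2806 of them shared with the 3051. Without HUA3 1721 genes changed and without XZSW2 1852.

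**Figure D3:**
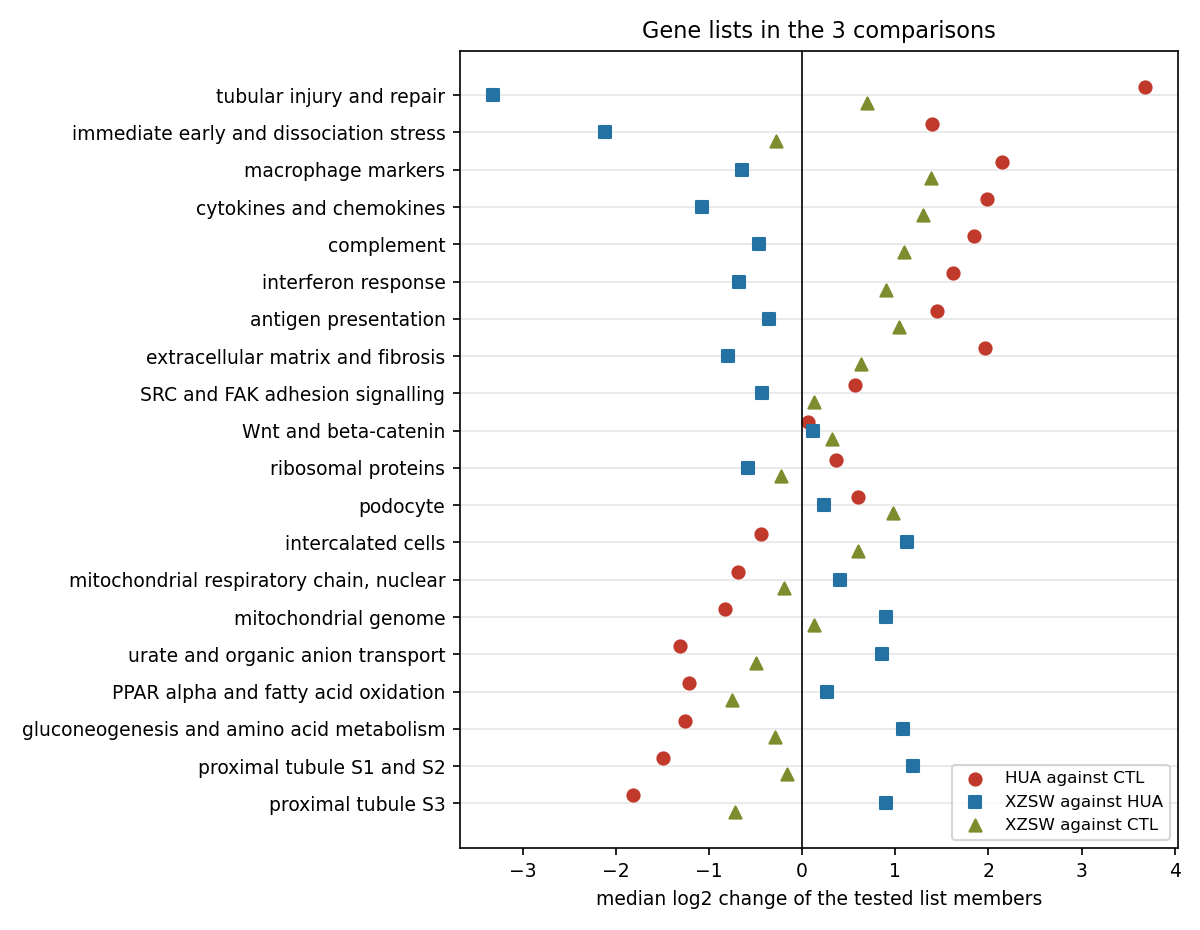
Median log2 change (horizontal axis) of the tested members of 20 gene lists (vertical axis) in HUA against CTL (circles), XZSW against HUA (squares) and XZSW against CTL (triangles). The injury list has medians of 3.69, -3.32 and 0.70, and the fatty acid oxidation list -1.21, 0.27 and -0.75.

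Of the 5488 genes that changed in HUA, 2309 (42.1%) changed in the opposite direction in XZSW against HUA, 1267 of them first up and then down and 1042 first down and then up; 7 changed again in the same direction. Independent lists of these sizes would share 426 genes in opposite directions. Both comparisons use the HUA libraries, which makes an apparent reversal by chance alone. A total of 20 simulated sets with unchanged groups gave 0.45 such genes on average and 3 at most. Their covariance of the log2 changes was -0.176, beside -0.853 in the data, a difference of -0.677. With no HUA effect in them, few genes can be called in these sets. Their count therefore cannot size the reversal by chance among genes that did change in HUA. With the HUA libraries split 2 and 2 between the comparisons, in 6 ways, 910 to 1974 genes reversed where independent lists would share 198 to 442. In the XZSW libraries the genes that rose in HUA had a median log2 change of 0.53 against CTL, beside 1.31 in HUA, and those that fell -0.36, beside -0.92. With the HUA libraries not used to choose the genes, these medians were 0.35 to 0.65 beside 0.70 to 1.58, and -0.37 to -0.29 beside -1.20 to -0.63. The same CTL libraries served to choose the genes and to measure them. By chance alone this moves both medians in the direction of the choice. Of the genes that changed in HUA, 405 that rose and 313 that fell also passed in the same direction in XZSW against CTL. Both of these comparisons use the CTL libraries. Without HUA3 1329 genes reversed and without XZSW2 1456.

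The comparison of XZSW with CTL asks how far treated kidneys still differed from controls. Some genes of fatty acid oxidation were lower in XZSW and some injury, complement and macrophage genes higher. In the PPAR alpha and fatty acid oxidation list 9 of 28 genes fell and none rose, 18 adjusted over the list alone, with a median log2 change of -0.75. Pdk4 fell from 527 ± 210.2 to 34.4 ± 17.7 CPM (mean ± SD, n = 4; log2 change -3.94, SE 0.51) and Angptl4 from 301 ± 72.4 to 55.8 ± 24.5 CPM, while Acot1, an acyl-CoA thioesterase, and Acadvl, the very long-chain acyl-CoA dehydrogenase, fell 3.19-fold and 1.63-fold (camera adjusted p = 2.51e-18, and adjusted p = 0.396 with an estimated correlation). Clu stood at 620 ± 105 CPM in XZSW and 166 ± 15.9 CPM in CTL, a rise of 3.74-fold. Over all genes 987 of 19772 changed, 538 upward and 449 downward.

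The largest rises were in Serpina3n (19.9-fold), an acute phase protease inhibitor, and Lcn2 (7.29-fold), whose values were spread over the XZSW libraries. Cd72, a receptor of B cells, rose from 1.87 ± 0.575 to 9.05 ± 1.62 CPM, and Ddn, a podocyte and neuronal protein, from 3.83 ± 0.64 to 14.3 ± 2.24 CPM. Aoc1, diamine oxidase, rose 3.83-fold, Gc, vitamin D binding protein, and Phf11b 4.001-fold and 4.007-fold, and the paralogs Serpina1a and Serpina1c, whose reads may be split between copies, 5.01-fold and 5.86-fold. The largest falls beside Pdk4 and Angptl4 were in Chac1 (20.8-fold), a glutathione-degrading enzyme, Actc1 (12.03-fold), Plk3 (7.05-fold), Ccl28 (6.41-fold), Cxcl1 (5.95-fold), Tmem252 (4.90-fold), Gadd45g (4.83-fold) and Slc22a26 (4.46-fold). Of these 20 genes 7 kept their call without any of the 12 libraries in turn, Cd72, Clu, Ddn, Pdk4, Plk3, Ccl28 and Angptl4, and 13 lost it without at least 1 of them. Without XZSW1 the log2 changes of Serpina3n, Lcn2, Serpina1c and Serpina1a were 2.70, 2.17, 1.61 and 1.54 in place of 4.31, 2.87, 2.55 and 2.32, and without CTL4 that of Chac1 was -2.14 in place of -4.38. Without XZSW4 those of Cxcl1 and Gadd45g were -3.25 and -2.95, and without XZSW2 that of Tmem252 was -3.05. With limma on log2(FPKM + 1) Serpina3n, Serpina1a, Serpina1c, Gc and Chac1 did not pass, and with the GC split as a further term Gc, Cxcl1, Gadd45g and Slc22a26 did not. With quantile normalization Serpina1a, Serpina1c, Phf11b and Gc did not pass. With TMM factors on the FPKM values Lcn2, Serpina3n, Serpina1a, Serpina1c, Gc and Chac1 did not, and Chac1 did not with limma on log2(FPKM) and a pseudocount of 0.1.

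Of 16 complement genes 6 rose and none fell, 7 and 2 adjusted over the list alone, with C3ar1 up 7.03-fold and C3 3.46-fold (camera adjusted p = 1.59e-05, and adjusted p = 0.297 with an estimated correlation). Of 20 macrophage markers 5 rose and 1 fell, 9 and 1 adjusted over the list alone, with Cx3cr1 up 4.23-fold, Cd68 3.17-fold and Itgam 8.34-fold (camera adjusted p = 2.21e-06, and adjusted p = 0.473 with an estimated correlation). Of 12 podocyte genes 5 rose and 1 fell, 9 and 1 adjusted over the list alone, with Nphs1 up 1.91-fold, Synpo 2.05-fold and Cdkn1c 2.92-fold (camera adjusted p = 1.07e-05, and adjusted p = 0.424 with an estimated correlation). Of 12 intercalated cell genes 2 rose, 3 adjusted over the list alone, among them Foxi1, their transcription factor, 2.96-fold (adjusted p = 0.486 with an estimated correlation). Of 12 distal tubule genes 3 rose, 4 adjusted over the list alone, among them the thiazide-sensitive cotransporter Slc12a3, 2.19-fold (adjusted p = 0.486 with an estimated correlation). Of 26 injury genes 3 rose, Clu, Krt18 and Lcn2, and 10 adjusted over the list alone (camera adjusted p = 0.000507, and adjusted p = 0.554 with an estimated correlation). Of 30 matrix genes 4 rose, 12 adjusted over the list alone, among them Col1a1, 6.96-fold, and Tnc, 7.87-fold (camera adjusted p = 0.000186, and adjusted p = 0.659 with an estimated correlation). With the GC split as a further term 1 rose and camera gave adjusted p = 0.167.

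None of the 20 S1 and S2 genes passed by edgeR's test, and none adjusted over the list alone, where Kap stood at 13588 ± 1135 CPM in XZSW and 26002 ± 2522 CPM in CTL (log2 change -0.94, SE 0.26, adjusted p = 0.053). The fit pools the spread of each gene over all groups, and HUA libraries differed more among themselves than CTL libraries did. A gene that did not pass here is thus not shown to be back at its CTL level. Of 12 S3 genes 1 fell, Atp11a, 1.74-fold, and 3 adjusted over the list alone, with a list median of -0.72 (camera adjusted p = 8e-05, and adjusted p = 0.486 with an estimated correlation). Of 16 urate and organic anion transport genes 3 fell, Slc17a1, Abcg2 and Slc17a3, by 1.67-fold, 1.56-fold and 1.73-fold, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00158, and adjusted p = 0.61 with an estimated correlation). In the fit with the GC split 1 fell and 1 rose, and camera gave adjusted p = 0.257. Slc22a12 stood at 812 ± 84.3 CPM in XZSW (log2 change -0.85, SE 0.23, adjusted p = 0.0531). Of 18 androgen-dependent genes 2 fell, Gusb and Slco1a1, 3.33-fold and 2.76-fold, and 11 adjusted over the list alone (camera adjusted p = 2.47e-06, and adjusted p = 0.396 with an estimated correlation). Of 22 interferon response genes 3 rose, 4 adjusted over the list alone, among them Stat2, 2.24-fold (adjusted p = 0.486 with an estimated correlation). None of 13 T and NK cell markers passed, also adjusted over the list alone. Camera called this list up (adjusted p = 0.0131, and adjusted p = 0.678 with an estimated correlation). None of 14 antigen presentation genes passed, 9 adjusted over the list alone (camera adjusted p = 9.45e-05, and adjusted p = 0.486 with an estimated correlation). In the fit with the GC split camera gave this list adjusted p = 0.076, and 2 interferon genes rose and no S3 gene fell. In all, camera called 23 of 48 lists, 14 up and 9 down, of which none held with an estimated correlation and 5 were called by fry.

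The number of genes that differed between XZSW and CTL depended on the libraries and on the test. It was 149 without CTL2, 183 without CTL3, 252 without XZSW3, 321 without CTL1, 326 without XZSW1, 342 without CTL4, 544 without XZSW4 and 1626 without HUA1, 2625 when the HUA libraries were left out of the fit, 2417 with DESeq2 and 4204 with array weights. With library-total scaling 1221 genes rose and 224 fell, and on the FPKM values 1188 rose and 188 fell. Within the 7 libraries without the GC trend, 2 of XZSW and 4 of CTL with HUA1, 3027 changed, and with the split as a further term 1750, 774 of them shared with the 987. With the split as a further term 3 macrophage and 3 complement genes rose, and with library-total scaling 9 matrix, 5 injury and 8 podocyte genes.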

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

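The splits into other groupings were chosen before the results were seen, and the 24 values below are those that a fixed rule on gaps between the 4 libraries of a group picked out of 331 groups, where 16.6 would be picked by chance. Of the 35 splits of 8 libraries 4 and 4, only the real grouping gave as many changed genes as observed, 1 of 35 in each comparison; the highest other split gave 0 genes in HUA against CTL, 0 in XZSW against HUA and 1 in XZSW against CTL, beside 5488, 3051 and 987.

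Mitochondrial genes took 13.5% of counts in XZSW3 and 16.7% to 17.2% in the other XZSW libraries. The ribosomal RNA gene CT010467 took 0.524% in HUA1 (others of HUA 1.29% to 1.44%) and 2.24% in XZSW3 (others of XZSW 0.159% to 0.466%). Haemoglobin genes took 0.0217% in HUA1 and 0.0021% to 0.0028% in the other HUA libraries. The score of the injury list was 0.39 in CTL4 (others of CTL -0.19 to -0.10), that of the apoptosis list -0.15 in XZSW2 (others -0.01 to 0.02) and that of the ribosomal protein list 0.12 in CTL4 (others -0.05 to -0.04).

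In log2(CPM + 0.5), Vgf was 7.90 in HUA3 (others of HUA 4.53 to 4.91) and Il1f6 7.86 in HUA3 (others 5.999 to 6.16). Slc25a25 was 4.996 in HUA3 (others 6.59 to 6.83). Among CTL libraries, where the others had 0 counts, Il1f6 was -0.48, Wnt7a -0.74, Mir6358 -0.84 and Ccl20 -0.52 in CTL2, and Sprr2g -0.83 in CTL3. In CTL3, Snx31 was 5.59 (others 5.11 to 5.19), Hpd 6.52 (others 7.80 to 7.93), Plk3 6.21 (others 7.21 to 7.36) and Gadd45g 7.01 (others 7.57 to 7.67). In XZSW1, Sprr2g was 1.06 (others of XZSW -0.65 to -0.60), Wnt7a 0.83 (others -1 to -0.79) and G0s2 4.18 (others 4.72 to 4.79). Lpl was 7.10 in XZSW3 (others 8.08 to 8.16) and Angptl4 6.54 in XZSW2 (others 5.38 to 5.51).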

How the results depend on the processing

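Library-total scaling, limma on log2(FPKM + 1) beside edgeR and the GC and length correction were chosen after the results were seen. So were the GC split as a further term, the fits within each side of it and the omission of XZSW1 for lists. The other settings were chosen before. For genes changed in XZSW against CTL, 987 here, the alternatives gave 1744 and 1791 on log2(FPKM) with pseudocounts of 0.1 and 0.01, 529 without a filter, 480 at a mean FPKM of at least 5, 472 with quantile normalization, 2625 on the 8 libraries of the comparison, 4204 with array weights, 2417 with DESeq2, 1750 with the GC split as a further term and 3027 within its low side. Requiring a mean FPKM of at least 5 gave 2920 genes in HUA against CTL and 1393 reversed. In XZSW against HUA the 8 libraries alone gave 1439 and the high side of the GC split 41, with 0 title genes. The main fit pools the spread of each gene over all groups. Between libraries of CTL the chi-square per degree of freedom was 25.8 to 60.0. It was 206 to 453 in HUA and 84.6 to 248 in XZSW. With HUA left out of the fit the count in XZSW against CTL was higher. With CTL left out the count in XZSW against HUA was lower. The cause of the differences between settings was not tested further, save that fewer genes are tested at a mean FPKM of at least 5.

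Leaving out each library in turn gave 4237 to 6347 genes in HUA against CTL, 1721 to 3858 in XZSW against HUA, 149 to 1626 in XZSW against CTL and 1329 to 2956 reversed. The lowest came without HUA3, and without CTL2 for XZSW against CTL, and the highest without HUA1. In XZSW against CTL it gave 321 without CTL1, 183 without CTL3, 342 without CTL4, 326 without XZSW1, 252 without XZSW3 and 544 without XZSW4; without XZSW2 it gave 1852 in XZSW against HUA and 1456 reversed. Title genes called ranged from 3 to 4 in HUA against CTL, 3 to 4 in XZSW against HUA and 0 to 1 (Spp1) in XZSW against CTL, and the log2 change between XZSW and CTL from -0.0900 to 0.0796 for Src and -0.0158 to 0.145 for Ptk2. With the HUA libraries split, 1064, 1338, 1379 and 910 genes reversed where HUA against CTL used HUA1 and HUA3, HUA1 and HUA4, HUA2 and HUA3, and HUA3 and HUA4.

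All 5 title genes were called in HUA against CTL with the pseudocount of 0.1, with library-total scaling and on log2(FPKM + 1), and 1, Spp1, in XZSW against CTL within the low side of the GC split. The uncalled log2 change of Src between XZSW and CTL was 0.22 with the pseudocount of 0.1, 0.0379 with quantile normalization, 0.15 with library-total scaling and 0.19 on log2(FPKM + 1), beside -0.01; that of Ctnnb1 was 0.0587 with the pseudocount of 0.1, 0.0883 with quantile normalization and 0.0577 on log2(FPKM + 1), beside -0.17. Lists called were 1, 1 and 0 in the 3 comparisons with an estimated correlation, 5 with fry and 14 with the GC split as a further term in XZSW against CTL, and 22, 28 and 24 without XZSW1. With the replicate number as a block 5466, 3076 and 813 genes changed, 23, 30 and 22 lists were called and 2351 genes reversed. Of the title genes 4 were called in HUA against CTL, with Ctnnb1 added (adjusted p = 0.0471), and of the named genes Serpina1a, Serpina1c, Phf11b and Gadd45g lost their call in XZSW against CTL (adjusted p = 0.0532, 0.0507, 0.075 and 0.0529). Of the same-numbered pairs 2 of 12 had a correlation over 0.1, with a range of -0.046 to 0.174, and 7 of 12 were highest with their own number. These values are low but do not decide whether the numbers pair the samples.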

Other observations

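The tests of the GC trend, of the proximal tubule list and of adipocyte genes were chosen after the patterns were seen; the GC and length correction was also chosen after the data were seen, with its bound for the fatty acid oxidation list set before that result was known, as was the bound of the clock test. Calcium and phosphate genes changed on several sides. The epithelial calcium channels Trpv6 and Trpv5 rose 10.5-fold and 5.88-fold in HUA against CTL, Vdr, the vitamin D receptor, and Fgf1 fell 2.15-fold and 2.13-fold, and Kl, the FGF23 co-receptor, named after its values were seen, fell from 547.8 ± 84.1 to 209.9 ± 97.6 CPM and stood at 574 ± 82.1 CPM in XZSW. Of the 14 vitamin D and mineral genes 3 rose and 6 fell in HUA, as adjusted over the list alone (camera adjusted p = 0.415). In XZSW against CTL Trpv6 remained 2.88-fold higher and Fgf1 1.76-fold lower. Of 14 thick ascending limb genes 4 fell and 1 rose in HUA, as adjusted over the list alone, with Egf down 8.45-fold and Kcnj1 3.16-fold (camera adjusted p = 0.0535), and of 12 collecting duct principal cell genes 3 fell and 2 rose, with Aqp3 down 3.88-fold (adjusted p = 0.169). Camera called both of these lists, thick ascending limb and collecting duct, down with the GC split as a further term. In the first 5 fell and 1 rose (camera adjusted p = 0.0118) and in the second 4 fell and none rose (camera adjusted p = 0.0263). In the fit without this term camera with an estimated correlation gave adjusted p = 0.647 and 0.574. Of 12 distal tubule genes 2 rose and 2 fell, with Pvalb down 4.19-fold (adjusted p = 0.486).

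Stress and metabolic lists were mixed in HUA against CTL. Of 19 cholesterol synthesis genes 8 rose and 3 fell, with Fdps up 3.04-fold and Cyp51 down 4.29-fold (camera adjusted p = 0.415), and of 22 glycolysis and hypoxia genes 6 rose and 5 fell, with Hk2 up 18.6-fold and Bnip3 down 2.37-fold (adjusted p = 0.874). Of 21 stress response genes 5 rose and 2 fell, with Asns up 7.84-fold and Ddit4 down 3.36-fold (adjusted p = 0.699), of 25 NRF2 genes 3 rose and 5 fell, with Srxn1 up 2.02-fold and Sod2 down 1.84-fold (adjusted p = 0.153), and of 12 osmotic response genes 2 rose, Hspb1, 39.9-fold, and Nfat5, 2.17-fold (adjusted p = 0.415). Of 18 clock genes 2 rose and 6 fell, with Tef down 2.93-fold (adjusted p = 0.122), of 14 targets of AhR, CAR and PXR 1 rose and 4 fell, with Por down 2.72-fold (adjusted p = 0.153), and of 13 glucocorticoid response genes 4 rose and 5 fell, with Mt2 up 12.9-fold; the last list had a median of -0.51, a mean of 0.78 and camera's direction up (adjusted p = 0.48). In the fit with the GC split as a further term 5 glucocorticoid response genes rose and none fell, with a median of 0.16. Camera called the list up there (adjusted p = 0.0388). In the fit without this term camera with an estimated correlation gave the list adjusted p = 0.7775. With library-total scaling 4 glucocorticoid response genes rose and none fell. With library-total scaling 6 NRF2 genes rose and 3 fell, with a median of 0.07 in place of -0.25. Other lists moved too. The fit with the GC split gave 4 rising and 3 falling for cholesterol synthesis, with a median of 0.02, and the same numbers for glycolysis and hypoxia. It gave 1 and 1 for AhR, CAR and PXR targets, with a median of -0.14 in place of -0.71, 3 and 2 for the stress response, 4 and 5 for the clock and 3 and 4 for vitamin D and mineral genes. Library-total scaling gave 2 rising and 2 falling for AhR, CAR and PXR targets, 8 and 2 for glycolysis, 2 and 3 for the clock and 4 and 0 for the osmotic response. In XZSW, 60 genes were higher than in both other groups and 69 lower, where independent lists would share 38.2 and 37.5. Both comparisons use the XZSW libraries, and 20 simulated sets with unchanged groups gave 2 at most. Few genes can be called in such sets, so this count cannot size the chance overlap among genes that did change. With the XZSW libraries split 2 and 2 between the comparisons the numbers were 0 to 6 and 0 to 11. Those lower included Jun, with log2 changes of -2.12 against HUA and -1.57 against CTL, and Pdk4, with -2.45 and -3.94, and those higher Slc12a3, with 0.94 and 1.13.

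The GC trend in 5 libraries may come from a batch of library preparation or sequencing, which no label gives; the gap of 0.163 between the sets of slopes cannot decide it. Tubular injury in the kidneys alone is not a likely cause, since 4 of 8 HUA and XZSW libraries were out of place between the slope and the injury score. HUA1 had an injury score of 3.70 and a slope of 0.0161.

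Lower fatty acid oxidation genes in XZSW than in CTL could come from bias in GC content or length. The list's median was -0.73 after correction for it, beside -0.75. Its score, in log2 units relative to CTL, was -0.773 and -0.637 in XZSW1 and XZSW2. It was -1.46 and -1.67 in XZSW3 and XZSW4, which have the GC trend. In HUA against CTL the correction left the median at -1.16, where the GC split as a further term gave -0.74. The correction thus does not settle what part of the fall goes with the split. Fewer proximal tubule S1 and S2 cells in the sample are not a likely cause, with a median of -0.16 for that list; the S3 list had a median of -0.72, so a smaller share of S3 cells stays possible. Another time of day at dissection was not decided, since the clock measure differed by 0.002 with an SE of 0.884.

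Of 12 adipocyte list members 11 had their highest value in XZSW1, with Fabp4 at 167 CPM and Adipoq at 14.0 CPM in that library. Fat tissue in the piece of kidney is a possible cause, but this count restates the pattern and does not test it, so the cause stays open.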
